A study of Homo sapiens with 2 samples.

How the data were processed

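Single-cell RNA sequencing was measured in 2 libraries of HES-2, an established human embryonic stem cell line. The groups were taken from the sample titles. One library came from cells grown on mouse laminin-111 without feeder cells (LN, 1 library), the other from conventional culture on mitotically inactivated mouse embryonic fibroblasts (primed, 1 library). The treatment label reads as conventional culture for both samples, which conflicts with the titles, so the direction of each comparison rests on the titles. Per the labels' protocols, dead cells were removed, viability was above 90%, 8000 cells were loaded for a predicted recovery of 5000, and version 3.1 of a droplet kit that counts 3' ends was used.

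The deposited matrices hold raw UMI counts, which are whole numbers of molecules per gene and barcode with no normalization by the authors, per the file headers and the values. Cell Ranger 6.1.2, Seurat 4.0.6 and the build GRCh38 are named in the submitters' processing notes, while the header of the matrices names software version 3.0.2. The annotation release and any filter on barcodes were not given in the sources used here. The matrices list 33538 genes, and 99.8% of their identifiers were found in GENCODE release 29 on GRCh38, from which coordinates and transcript GC content were taken. GPX1 and H19, each in 1 of the gene lists, were not among the features. Counting was against human genes, so mouse cells, if present, would be seen through the part of their RNA that was assigned to human genes.

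The LN matrix held 7384 barcodes and the primed matrix 8461, both above the predicted recovery. Cells with at least 1000 genes and at most 15% mitochondrial UMIs were kept, which left 7106 and 7925. Each library was clustered alone with scanpy 1.11.5 after scaling to 10000 counts, log1p, 2000 variable genes, 30 principal components and 15 neighbours, by the Leiden method at resolution 0.5. A cluster was named only from markers. The markers, the gene lists, the cell filter, the size rules and the rule for named genes were fixed before the data were examined. The scoring rule for clusters was set afterwards: at least 3 markers at 4-fold or more over the other cells and 20 CPM, or at least 6 of the 11 pluripotency markers detected in 50% of the cells, provided that the 10 leading genes held no more markers of another class than of pluripotency and that the cluster was not shallow. It left primed cluster 1 unnamed, with 21.3% of primed cells. Scrublet marked 1 LN cell and 0 primed cells as doublets, so doublet calling had not worked, and no doublets were removed.

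UMI counts were summed over the cells of each library, leaving out the fibroblast-like cluster, and divided by the library total to give counts per 1 M UMIs (CPM). The sums held 138156069 UMIs from 7106 LN cells and 148533172 UMIs from 7551 primed cells. With 1 library per group there was no test and no check on replicates. Intervals are 95% and exact (Poisson for a sum, conditional binomial for a ratio, binomial for a share of cells), and they cover counting error only. A gene was counted where it reached 10 CPM in the higher library and a ratio of at least 2. In gene lists, members of at least 5 CPM were measured, those at least 1.5-fold apart were counted, and the median log2 ratio was placed among 10000 random lists of equal size matched on expression in 20 bins, as a description of these libraries.

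The named genes followed 1 rule. It took the 15 genes in each direction with the largest ratio by the bound nearest 1, among genes of at least 20 CPM and 2-fold. It left out mitochondrial, ribosomal protein, clone-like and some sex chromosome genes. It added up to 4 members of each of 35 lists at 10 CPM or more with the largest ratio, and 14 fixed genes. A gene named outside the rule is marked as chosen after its values were seen. 1 gene that met the rule is not reported here.

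Shares of cells with a UMI, phase scores and variance over mean were computed on cells thinned to 5000 UMIs, which left out 179 LN and 109 primed cells. Feeder RNA in the pooled primed cells was estimated from 4 fibroblast markers that were under 1 CPM in LN, as the median ratio of their pooled level to their level in the fibroblast-like cells. This gave 0.164%, with single markers from 0.0853% to 5.95%. The ratio step was tested on simulated sums of 7991 genes with 200 changed. It called 100% of genes changed 2.5-fold, 4-fold or to 0.4 of their level at the 2-fold rule and 0% of those changed 1.5-fold, and 95.8% of intervals held the true ratio. On simulated cells, a variance over mean of 2 came out at a median of 2.00 in 200 genes.

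Alternatives covered library scaling (TMM from edgeR 4.0.16 in R 4.3.3, and median-of-ratios), equal weight per cell, thinning, cell filters, the clusters used, doublets, cell cycle phase, expression minimums and the size rule. Further alternatives were added after the data were seen. The planned median-of-ratios factors came out at 1 for both libraries, because ties among low-count genes set the median over 23517 genes. A version over measured genes was therefore added, and both are given. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6 were used. Genes with near-identical copies are uncertain, since UMIs can be split between them. These are LEFTY1 and LEFTY2, the metallothioneins, the actins ACTA1 and ACTG2, and MTRNR2L8, which resembles mitochondrial ribosomal RNA.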

Results

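The transcriptome of HES-2 cells was measured in 1 library from laminin-111 culture (LN) and 1 from conventional culture on mouse feeders (primed). LN cells received FGF2 at 20 ng/ml in medium with B27 and N2 supplements, and primed cells 10 ng/ml in medium with 20% serum replacement. The pooled cells had a median of 17474 UMIs and 4542 genes in LN and of 17668 UMIs and 4464 genes in primed. The median share of mitochondrial UMIs was 5.09% in LN and 2.52% in primed. Medium, matrix, FGF2 dose and feeders differed together, so a difference belongs to the pair of libraries as a whole. There were no replicates.

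The first comparison asked which genes differ between the cultures. Of 8438 genes measured, 110 were at least 2-fold higher in LN and 100 were at least 2-fold higher in primed. With TMM scaling the counts were 81 and 120, and with median-of-ratios scaling 77 and 121. LN calls were therefore 52.4% of all calls by total counts, 40.3% by TMM and 38.9% by median-of-ratios. The median log2 ratio of all measured genes was 0.05 by total counts and -0.06 by median-of-ratios, and list medians near these values have no firm direction.

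Among the genes higher in LN, LHFPL6 was at 50.9 CPM (95% interval 49.7 to 52.1) in LN and 11.4 CPM (10.9 to 12.0) in primed, a log2 ratio of 2.16. The calcium channel subunit CACNG8 (2.10), PKIB (2.03), PPP1R17 (2.00) and RIPOR2 (1.98) followed. FABP7, a fatty acid binding protein of neural progenitors, had a log2 ratio of 1.94, and POU3F1, a transcription factor of the early post-implantation epiblast, one of 1.78. DUSP6, a phosphatase that restrains ERK, stood at 91.8 CPM (90.2 to 93.4) in LN and 28.6 CPM (27.8 to 29.5) in primed. DUSP6 was uneven in LN, at 150 and 161 CPM in clusters 1 and 3 but 41.4 and 39.6 CPM in clusters 0 and 2. LN clusters 4, 5 and 6 were at 75.3, 351 and 46.5 CPM. The pooled primed clusters ran from 20.4 CPM in cluster 5 to 47.7 CPM in cluster 7. Other genes higher in LN were TMEM59L (1.88), IGDCC3 (1.75), VGF (1.68), SREBF1 (1.68), HMGCS1 (1.66) and MTRNR2L8 (1.62), the last uncertain because of its copies.

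The genes higher in primed were led by LEFTY2, a secreted inhibitor of NODAL, on chromosome 1 from 225936598 to 225941489. It was at 77.2 CPM (75.8 to 78.6) in primed and 0.384 CPM (0.287 to 0.502) in LN, a log2 ratio of -7.65 (-8.07 to -7.26). Its neighbour LEFTY1 had a ratio of -5.48, and NODAL itself stood at 37.7 CPM (36.7 to 38.7) in primed and 3.03 CPM (2.74 to 3.33) in LN. CER1, a secreted inhibitor of NODAL, BMP and WNT, had a ratio of -6.85. In pluripotent-like clusters alone the ratios were -7.53 for LEFTY2, -5.64 for LEFTY1, -3.80 for NODAL and -5.83 for CER1. Here and below, that set leaves out the mesendoderm-like cells, the LN neuroectoderm-like cells and also the unnamed primed cluster 1. CER1 was carried by few cells. The 89 mesendoderm-like primed cells held 3035 CER1 UMIs, at 1572 CPM. Primed cluster 4 was at 22.5 CPM, and primed clusters 0, 1, 2, 3 and 5 were at 1.04 to 2.05 CPM. In LN the neuroectoderm-like cells held 15 CER1 UMIs, at 27.4 CPM, against at most 0.249 CPM in the other LN clusters. NPPB (-4.26) and CST1 (-4.22) depended on the cells used, with -2.01 and -0.66 in pluripotent-like clusters alone.

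Other leading genes higher in primed were ACTG2 (-3.23) and ACTA1 (-2.40), which encode muscle actins, CAV1 (-2.89), a protein of caveolae, and ABHD12B (-3.17). MT1H, a metallothionein, had a ratio of -2.58, SGK1 of -2.18, LRAT, which esterifies retinol, of -2.03 and FOXB1 of -1.99. S100A6 had a ratio of -2.05, which became -0.12 once the estimated feeder RNA was subtracted, an alternative added after the data were seen.

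**Figure D1:**
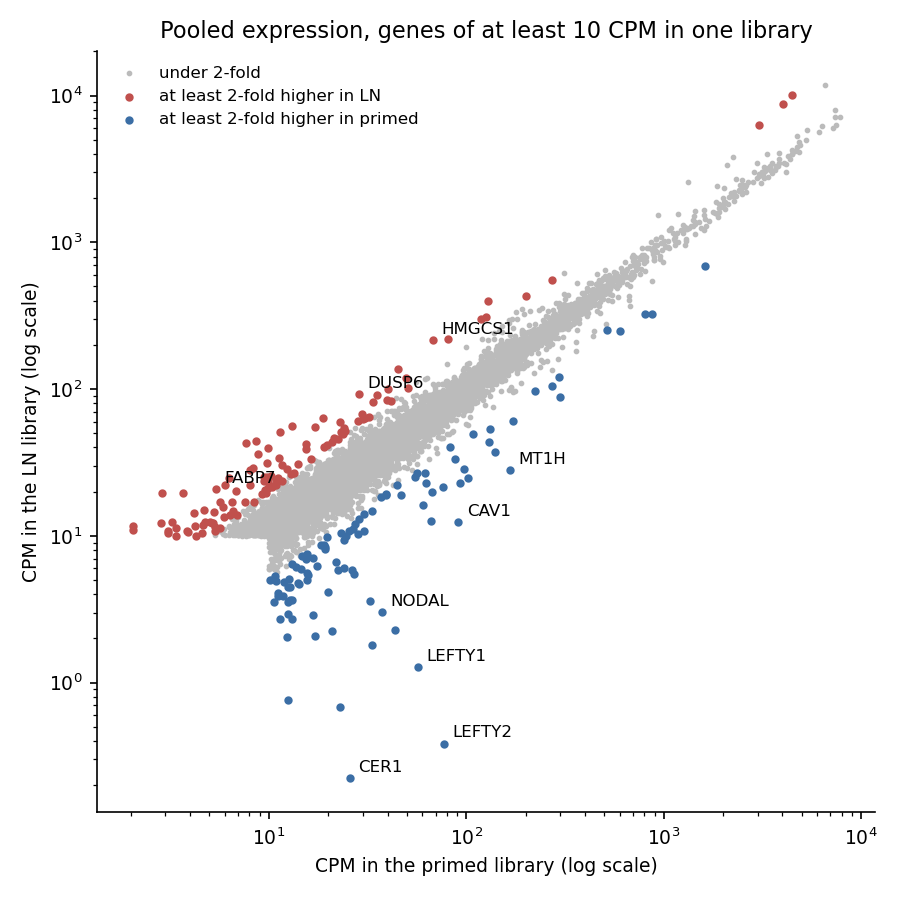
Pooled CPM per gene in the primed library (x, log scale) and the LN library (y, log scale) for genes of at least 10 CPM in one of them, with genes at least 2-fold apart in colour. LEFTY2 lies lowest against its primed level, at 77.2 CPM in primed and 0.384 CPM in LN.

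Pluripotency genes were compared next, since the series title names early post-implantation epiblast as the state of interest. Of 18 measured core pluripotency genes, 2 were at least 1.5-fold higher in LN (PODXL 0.87, TRIM71 0.74) and 2 lower (UTF1 -1.45, FOXD3 -0.97). POU5F1 was at 965 CPM (960 to 970) in LN and 1143 CPM (1138 to 1149) in primed, SOX2 at 524 and 430 CPM, and NANOG at 57.9 and 59.9 CPM. The core median of 0.03 was -0.04 in pluripotent-like clusters alone. In the formative epiblast list, 6 of 18 were higher in LN and 2 lower, with a median of 0.17 at percentile 98.2. The 6 were POU3F1, TCF15 (1.09), MYC (0.97), SOX3, ETV4 and ETV5, of which SOX3, ETV4 and ETV5 were named after their values were seen, while the 2 lower were UTF1 and FOXD3. OTX2, also in that list, was 80.7 CPM in LN and 110 CPM in primed, and DNMT3B 560 and 567 CPM.

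Of 22 measured primed-state genes, 5 were higher in LN and 4 lower, with a median of 0.22 at percentile 100. They included DUSP6, SALL1 (1.10) and SFRP2 (1.02) on the higher side and LGALS1 (-1.82) on the lower. LGALS1 was uneven in primed, since cluster 4, at 259 CPM, held 64.9% of its pooled primed UMIs. It was at 22.6 to 53.2 CPM in primed clusters 0, 1, 2, 3 and 5, against 21.6 CPM in LN. Just 5 of the 27 naive-state genes were measured, with 0 higher in LN and 2 lower, SOX15 (-1.27) and KLF5, which was named after its value was seen. KLF17, a naive marker, had 2 UMIs in LN and 4 in primed, and FGF5, a formative marker, had 1 and 4, so neither could be compared at this depth. DPPA3 was at 0.499 CPM in LN and 3.01 CPM in primed. ZIC2 differed little, at 185 and 193 CPM.

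Signalling lists were set beside these. In the NODAL list 6 of 15 genes were lower in LN and 0 higher, with a median of -0.51 at percentile 0. In the FGF-ERK list 5 of 18 were higher and 1 lower, with a median of 0.33 at percentile 99.9. PHLDA1 (0.87) and MYC were among the higher, and DUSP4 (-1.03) was the lower. MYC, ETV4 and ETV5 counted as higher in both this list and the formative list, so these lists are not independent. BMP targets had 3 of 7 lower and 0 higher, including ID1 (-0.88) and BAMBI (-0.67). BMP2 (-0.61) turned to 0.46 in pluripotent-like clusters alone, where the list median moved from -0.54 to -0.12. WNT targets had 1 of 5 higher (ZNRF3, 0.65) and 0 lower, and YAP-TEAD targets 1 of 11 higher (AXL, 1.14) and 0 lower.

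Genes of other lineages followed. In the primitive streak and mesendoderm list 5 of 7 measured genes were lower in LN and 1 higher, with a median of -3.66. SOX17 had 5 UMIs in LN and 900 in primed. The 89 mesendoderm-like primed cells held 863 of these 900, and primed clusters 0, 1, 2, 3, 4 and 5 were at 0.178 to 0.345 CPM. In pluripotent-like clusters alone the same 7 genes had a median of -2.50, and without the fibroblast-, mesendoderm- and neuroectoderm-like clusters one of -2.56, with 5 lower in both. Just CER1, KDR and HAS2 still reached 5 CPM without those clusters, and their median was 0.69. TBXT was at 0.181 CPM in LN and 0.451 CPM in primed, and PAX6 at 0.536 and 0.942 CPM. In the neuroectoderm list 1 of 3 was higher in LN (FABP7), and of 7 amnion and surface ectoderm genes 0 were 1.5-fold apart. TFAP2A stood at 5.06 and 6.92 CPM, and its log2 ratio of -0.45 was 0.63 in pluripotent-like clusters alone. That set leaves out primed cluster 1, which held 665 of the 1028 primed UMIs of TFAP2A and was kept out because TFAP2A was among its leading genes. The primordial germ cell list had 1 of 5 higher and 2 lower.

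Lipid synthesis was examined next. In the cholesterol list 13 of 25 genes were at least 1.5-fold higher and 1 lower, with a median of 0.66 at percentile 100. HMGCS1, an early enzyme of the pathway, was at 215 CPM (212 to 217) in LN and 68.2 CPM (66.8 to 69.5) in primed. INSIG1 had a ratio of 1.58, LSS of 1.33 and ACAT2 of 1.10. In the fatty acid list 9 of 14 were higher and 0 lower, with a median of 0.86 at percentile 100. ACSS2, which makes acetyl-CoA from acetate, had a ratio of 2.76, the transcription factor SREBF1 1.68, FASN 1.43 and FADS2 1.37.

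Of 13 genes encoded by the mitochondrial genome, 12 were at least 1.5-fold higher in LN and 0 lower, with a median of 0.96. MT-CO3 was at 10140 CPM in LN and 4491 CPM in primed, and MT-CO1 had a ratio of 1.12. The 48 nuclear genes of the respiratory chain did not follow, with 0 at least 1.5-fold apart and a median of -0.13. In glycolysis 3 of 22 genes were lower in LN and 0 higher, with a median of -0.15. LDHA, lactate dehydrogenase, was at 693 CPM (689 to 697) in LN and 1630 CPM (1624 to 1637) in primed, and SLC16A3, a lactate transporter, had a ratio of -1.03.

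Metallothioneins and metal transport genes had 8 of 12 members lower in LN and 1 higher, with a median of -0.85. MT1G (-1.77), MT1E (-1.57) and MT2A (-1.50) were among the lower. The integrated stress response list had 6 of 20 higher and 0 lower, with a median of 0.47. ATF4, its main transcription factor, had a ratio of 0.82, ATF5 of 1.05 and SESN2 of 1.02. In pluripotent-like clusters alone 10 were higher. Of 14 p53 targets 2 were higher and 1 lower. CDKN1A, an inhibitor of the cell cycle, was at 12.4 CPM in LN and 3.24 CPM in primed. The heat shock, unfolded protein response, S phase and G2/M lists had 0 of 12, 0 of 12, 0 of 42 and 0 of 54 genes 1.5-fold apart.

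The basement membrane and laminin receptor list, which bears on the matrix, had 2 of 23 genes higher in LN (DAG1 0.74, ITGA7 0.59) and 2 lower (FN1 -1.89, ITGB5 -0.72). Fibroblast and mesenchyme genes had 6 of 9 lower and 1 higher, with a median of -0.88. COL5A2 had a ratio of -2.60 and TAGLN of -1.29, while COL1A1 was the 1 higher, at 0.91. The fibroblast-like cells outside these sums made up 4.72% of primed cells.

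**Figure D2:**
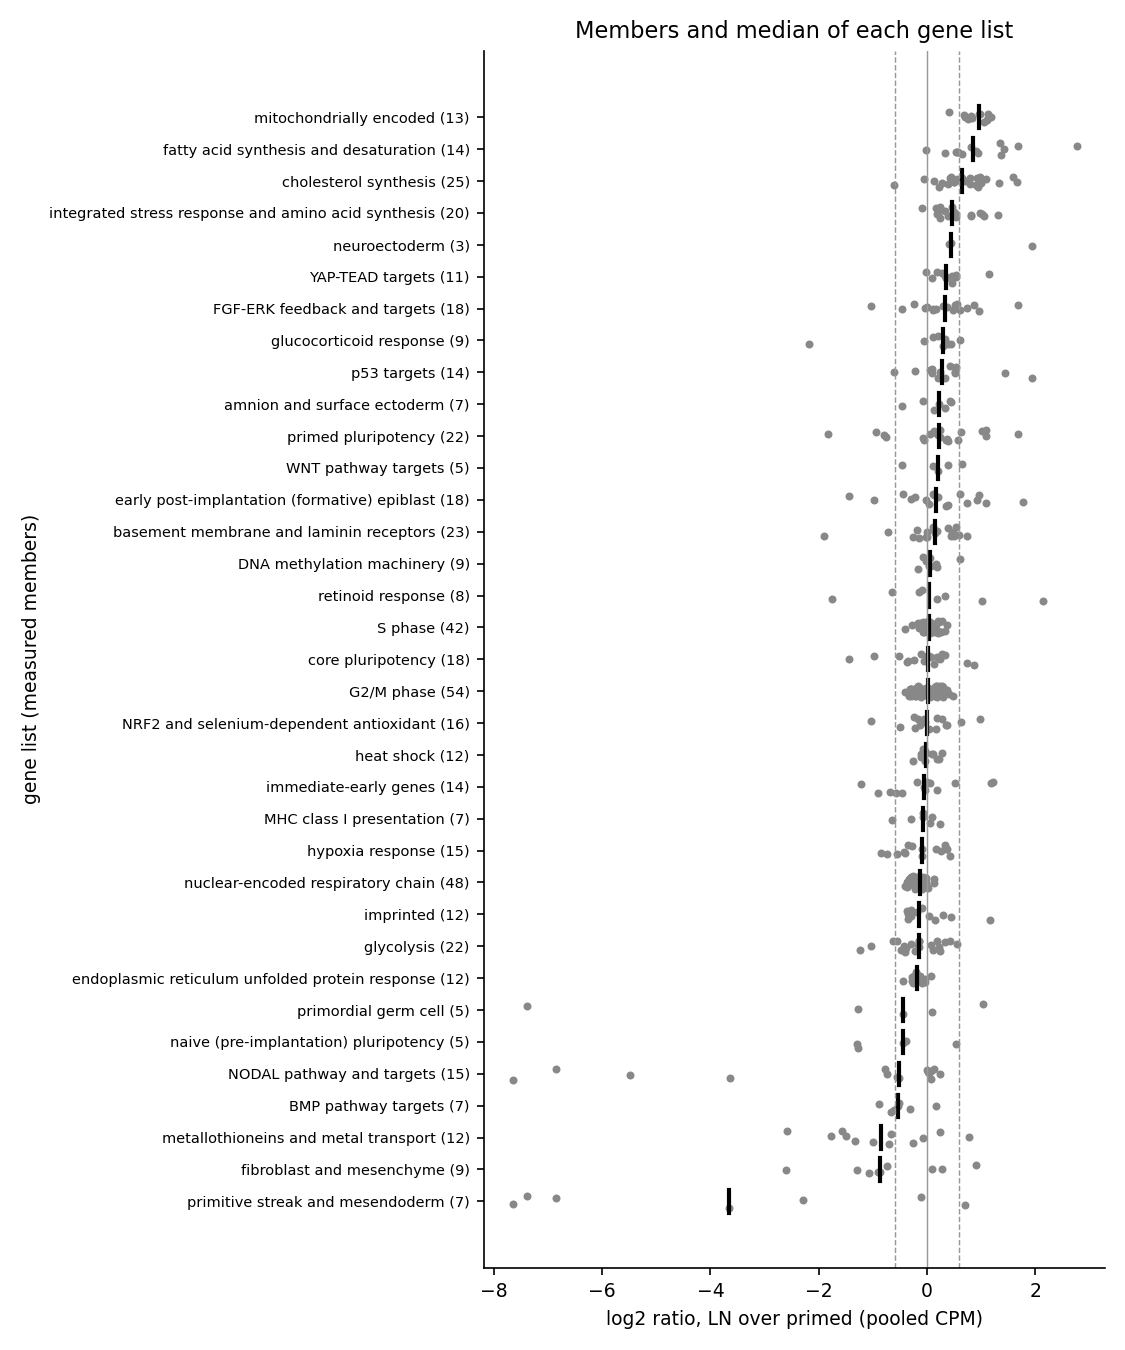
Log2 ratio of LN over primed pooled CPM (x) for each measured member of the 35 gene lists (y), with the number of measured members in brackets. Points are genes, vertical bars the list medians, and dashed lines 1.5-fold. The mitochondrially encoded list has a median of 0.96 and the primitive streak list one of -3.66.

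Cell classes were then compared. In LN, 7064 of 7106 cells (99.4%, 95% interval 99.2 to 99.6) lay in pluripotent-like clusters and 42 (0.591%, 0.426 to 0.798) in a neuroectoderm-like cluster that held SIX3, SIX6, LHX2 and FABP7. In primed, 5777 of 7925 cells (72.9%, 71.9 to 73.9) were pluripotent-like and 1685 (21.3%, 20.4 to 22.2) lay in the unnamed cluster 1, which had all 11 pluripotency markers but also TFAP2A among its 10 leading genes. A further 374 (4.72%, 4.26 to 5.21) were fibroblast-like with COL1A1, COL3A1 and PRRX1, and 89 (1.12%, 0.903 to 1.38) were mesendoderm-like with SOX17, EOMES and GATA4. Each of these last classes had 0 of 7106 LN cells, with an upper limit of 0.0519% from counting alone. The limit does not cover cells that clustering fails to separate. At resolution 1.0, 0 LN cells were neuroectoderm-like with the same limit, against 42 here. That resolution had an unnamed LN cluster of 162 cells led by SIX3, DLK1 and PRTG, which also led the 42 cells. The name was thus lost, but a cluster with these leading genes was still found. No naive-, germ cell- or amnion-like cluster was found in either library. When both libraries were clustered together, 93.9% of primed cells were pluripotent-like, so the unnamed share depends on the clustering. LN cluster 6 (339 cells) had a median mitochondrial share of 0.126%. Mitochondria-poor cells were not confined to LN. Of the pooled cells, 4.91% in LN and 4.44% in primed were under 0.5% mitochondrial UMIs. At resolution 0.3 a primed cluster of 175 cells had a median of 0.081%. Joint clustering put 337 LN and 157 primed cells in the same mitochondria-poor cluster. The leading genes of LN cluster 6 depended on the clustering, with GDF15 and AREG first here. ROMO1 and RPL31 were first among 317 such LN cells at resolution 0.3. With the stricter cell filter GDF15 and AREG led 18 LN cells apart from 79 others of low mitochondrial share.

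The share of cells with a UMI was compared for the NODAL group after thinning. LEFTY2 had a UMI in 0.202% of LN cells (0.111 to 0.339) and 15.2% of primed cells (14.4 to 16.0). The share was 5.53% in the fibroblast-like cells (3.06 to 9.11). NODAL had a UMI in 1.5% of LN cells (1.23 to 1.82), 12.0% of primed cells (11.3 to 12.7) and 3.56% of fibroblast-like cells. Without thinning the shares of LN and primed cells were 0.577% and 30.9% for LEFTY2 and 5.05% and 27.8% for NODAL. DUSP6 went the other way, with 29.9% of LN and 12.2% of primed cells. POU5F1 had a UMI in 98.8% and 98.7%. The fibroblast-like cells had a median depth of 6564.5 UMIs before thinning. They were all from the primed library, so their shares give no background for LN. They give no clean background for primed either, since POU5F1 was at 482 CPM in them. With the stricter cell filter the 96 fibroblast-like cells had a median of 21234.5 UMIs and all 11 pluripotency markers in at least 50% of cells.

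**Figure D3:**
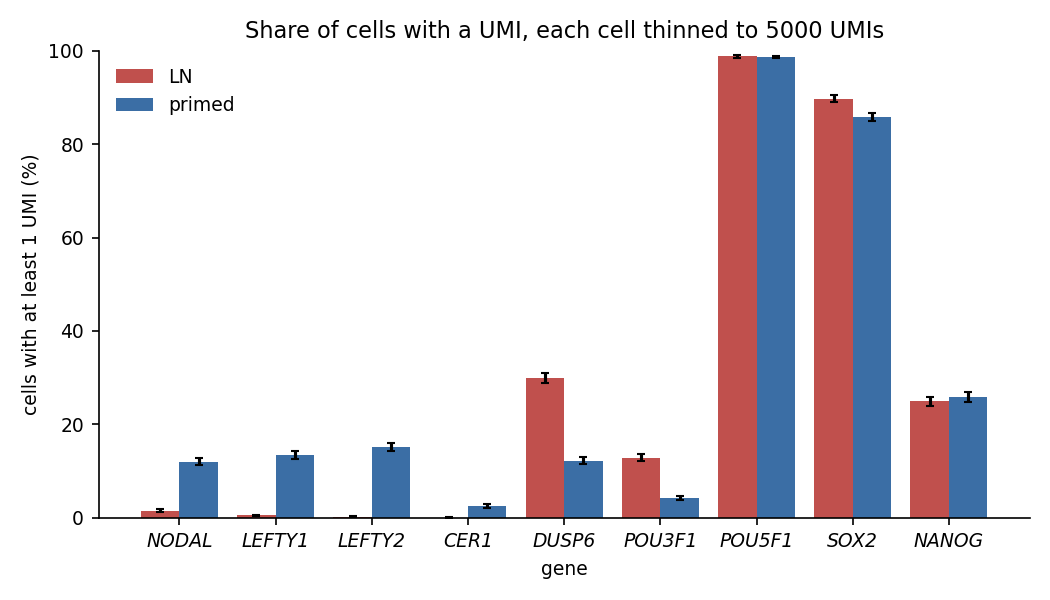
Share of cells with at least 1 UMI (y, percent, from 0) for each gene (x) in LN and primed cells thinned to 5000 UMIs, with exact 95% binomial intervals that cover counting error. LEFTY2 reaches 15.2% of primed and 0.202% of LN cells, and POU5F1 98.8% of LN and 98.7% of primed cells.

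Cell cycle phases did not give a stable order. The S share was 50.5% in LN and 56.2% in primed, and the G2/M share 49.0% and 41.7%. Thinned to 2500 UMIs, the S shares were 51.3% and 46.5%, in the opposite order. G1 was called in 34 LN and 154 primed cells. No cycling was read from these calls, and the S and G2/M lists had medians of 0.04 and 0.02.

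Cell-to-cell variation was compared to see whether one culture was more uniform. Over 5493 genes the median variance over mean was 1.03 in both libraries, and 49.4% of genes varied less in LN. At 5000 UMIs per cell this median lies close to the value of 1 that counting alone gives, so it cannot show which culture was more uniform. A value above 1.5 was found for 95 genes in LN and 119 in primed. HMGCS1 and SQLE varied more in LN, with log2 ratios of variance over mean of 1.08 and 0.47, while S100A6 and TAGLN varied more in primed, with -3.07 and -1.66. Each of these 4 genes also had its higher level in the library where it varied more, and variance over mean rises with the level. SQLE was chosen after its value was seen.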

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

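The tests of feeder RNA and of a subset of primed cells on fibroblast genes, and the test on S100A6, were chosen only after the values were seen. Fibroblast-like cells made up 4.72% of the primed library and were left out of the pooled sums, so theirs is a signal outside the main measurement. LN had 0 of 7106, and the labels put mouse fibroblasts under the primed cells alone.

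The 6 fibroblast and mesenchyme genes lower in LN were COL5A2, TAGLN, PDGFRA, COL6A1, COL6A2 and COL1A2. The estimated feeder share accounted for a median of 0.337% of their primed level. That argues against feeder RNA as the whole cause for TAGLN, PDGFRA, COL6A1 and COL6A2. The estimate is loose, with single markers from 0.0853% to 5.95%, and it does not decide COL1A2 and COL5A2. These were at 470 and 189 CPM in the fibroblast-like cells and at 25.4 and 12.4 CPM in the pooled primed cells. At the share of the highest marker, feeder RNA could account for their difference. A subset of the primed cells stays open for the 6 genes as a set. Primed cluster 4 held a median of 33.4% of their UMIs and 19.1% of all UMIs, between the bounds set for and against it. The members differed, with 59.6% of COL5A2, 54.3% of TAGLN and 40.0% of COL1A2 UMIs in cluster 4. COL6A2 had 26.9%, COL6A1 24.0% and PDGFRA 22.1%, nearer the share of all UMIs. TAGLN was at 2277 CPM in cluster 4 and at 329 to 560 CPM in clusters 0, 1, 2, 3 and 5, against 327 CPM in LN. A first version of the cluster 4 test added S100A6, LGALS1, CAV1, ACTG2 and ACTA1 after their values were seen. It gave a median of 54.3% and is not relied on, because CAV1 was known to lead cluster 4. The culture conditions remain open as an untested biological explanation.

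S100A6 had a log2 ratio of -2.05 (-2.10 to -1.99), and -0.12 once feeder RNA was subtracted, because the estimate accounts for 73.7% of its primed level. That estimate is loose, with single markers from 0.0853% to 5.95%, and the primed cluster with least S100A6 reached 67.8% of the level it gives. S100A6 was uneven, at 258 CPM (253 to 264) in primed cluster 4 and 473 CPM (443 to 505) in cluster 7 against 50.9 CPM (48.4 to 53.4) in cluster 1, which free RNA that reaches all droplets alike would not give. With the UMIs per cell of the cluster with fewest taken from every primed cell, the ratio was -1.13, and -1.03 with their upper limit. That argues against free feeder RNA as the whole cause in the pooled cells. The UMIs left lay mainly in clusters 4 and 7, which had 6.09 and 10.3 UMIs per cell before the subtraction. Clusters 0, 1, 2, 3 and 5 had 0.942 to 1.42, so free feeder RNA stays open as the source of much of their S100A6. Feeder material attached to some cells was not tested and stays open, as do the culture conditions.

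In LN, 1 barcode outside the cell filter held 277 UMIs of PGC, a stomach pepsinogen, among 531 UMIs in all, with 48 UMIs of PGA5 and 39 of LIPF. PGC had 286 UMIs over all LN barcodes and 6 over all primed barcodes. These genes were chosen after their values were seen.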

How the results depend on the processing

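The alternatives without the fibroblast-, mesendoderm- and neuroectoderm-like clusters, without cells under 0.5% mitochondrial UMIs, without the 6% highest Scrublet scores, with feeder RNA subtracted, with the GC trend removed and with median-of-ratios over measured genes were chosen after seeing the data. The rest were planned. Of 153 named genes with values, 91 were at least 1.5-fold apart. Of these, 90 kept their direction and 75 stayed at least 1.5-fold apart in all 17 settings other than G1 cells alone. No paired analysis was possible because each group has 1 library and there was no test. The cause of each change below was not tested, unless fewer cells or another minimum or fold made it.

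Scaling changed the split of calls: 81 higher in LN and 120 in primed by TMM, 77 and 121 by median-of-ratios, and 92 and 109 by median-of-ratios over measured genes. The other size rules gave 437 and 272 genes at 1.5-fold and 30 and 40 at 3-fold, by construction. A minimum of 1 CPM gave 411 and 306 genes, and 50 CPM gave 32 and 31. With 50 CPM fewer members were measured, which left 3 NODAL genes lower and 2 formative, 8 cholesterol, 5 fatty acid and 3 stress response genes higher, and a fibroblast median of 0.19. Only cells called G1 rested on 34 LN and 154 primed cells and gave 1054 and 797 genes, 10 primed-state, 6 mitochondrially encoded and 14 stress response genes higher, 4 metallothionein genes lower, and a variance over mean median of -0.0564. There DAG1 (-0.27), PSMB8 (0.50), DPPA3 (0.66), CRABP1 (0.64), COL1A1 (-0.46) and JUNB (0.44) changed sign. In pluripotent-like clusters alone 10 stress response genes were higher, BMP2 was at 0.46 and the variation median was 0.0029. Without the fibroblast-, mesendoderm- and neuroectoderm-like clusters BMP2 was at 0.10 and the primitive streak median was 0.69. That median rests on the 3 genes still measured, which made the change, since the 7 genes of the main analysis had one of -2.56 there and of -2.50 in pluripotent-like clusters alone. CST1 was at -0.45 without those clusters, and S100A6 at -0.12 with feeder RNA subtracted. With a mean of at least 0.5 the variation median was 0.0034.

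At resolution 1.0 the neuroectoderm-like share of LN was 0, and the pluripotent-like shares were 86.1% in LN and 69.1% in primed. The unnamed LN cells there were a cluster of 162 led by SIX3 and one of 825 with all 11 pluripotency markers. The 825 cells were kept out because IGFBP3, an amnion or surface ectoderm marker, was among their leading genes. The fibroblast-like share was 6.35%, which includes 130 cells named for COL5A2, TWIST1 and TAGLN that had all 11 pluripotency markers. Resolution 0.3 gave 80.2% pluripotent-like in primed, and joint clustering 93.9%. With all barcodes the pluripotent-like shares were 97.3% and 66.0% and the fibroblast-like share 7.75%. The latter joins a cluster of 440 cells with 2 pluripotency markers and one of 216 cells with all 11. The 216 cells, at a median of 20438.5 UMIs, were named for COL5A2, TWIST1 and TAGLN. The stricter cell filter left 1.31% fibroblast-like cells. These had all 11 pluripotency markers and a median of 21234.5 UMIs, against 3 markers and 6564.5 UMIs in the main fibroblast-like cluster. They were thus not free of pluripotency transcripts. The LN minus primed difference in S share was -10.3 points with no thinning, -1.76 with the stricter filter and 4.77 when thinned to 2500 UMIs. That in G2/M share was 11.8, 3.34 and -5.00, and 5.45 without the top 5% of cells by UMIs. Shares of cells with a UMI follow depth by construction. When thinned to 2500 UMIs, LEFTY2 was in 0.0989% of LN and 9.68% of primed cells and NODAL in 0.749% and 7.28%. With no thinning LEFTY2 was in 0.577% and 30.9% and NODAL in 5.05% and 27.8%. Depth limits genes such as KLF17 and FGF5, with at most 4 UMIs per library.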

Other observations

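The test of free RNA on mitochondrial transcripts, the test of mesendoderm-like cells and the test of a shared axis were chosen only after the values were seen. Some lists stood outside the main comparisons. Retinoid response genes went both ways, with 2 of 8 higher in LN and 2 lower. CYP26A1, which breaks down retinoic acid, stood at 28.7 CPM in LN and 97.3 CPM in primed. Hypoxia response genes had 2 of 15 lower (BNIP3 -0.85, EGLN3 -0.74) and 0 higher, glucocorticoid response genes 1 of 9 lower (SGK1) and 1 higher (FKBP5 0.60). Immediate-early genes had 2 of 14 higher and 3 lower, with JUN at -1.21 and JUNB at -0.68. The antioxidant list had 2 of 16 higher (SLC7A11 0.99, HMOX1 0.62) and 1 lower (SELENOP -1.04). Imprinted genes had 1 of 12 higher and 0 lower, DNA methylation genes 1 of 9 higher (TET3 0.62) and 0 lower, and MHC class I genes 0 of 7 higher and 1 lower (PSMB8 -0.64).

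Mitochondrially encoded transcripts were higher in LN. Damaged cells would hold the excess in shallow cells, but in the 25% of cells with most UMIs the median mitochondrial share was 4.74% in LN and 2.37% in primed, a ratio of 2.00. Free RNA would reach mitochondria-poor cells too, but LN cluster 6 had a median of 0.126%, against a difference of 2.56 points between the libraries. Both values argue against these explanations as the whole cause. The culture conditions, dissociation and differences between single libraries remain open and untested.

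NODAL, LEFTY1, LEFTY2 and CER1 were lower in LN. Mesendoderm-like cells in the primed library do not account for all of it. With pluripotent-like clusters alone, 4 of the 4 genes stayed at least 1.5-fold lower in LN. That set also leaves out the LN neuroectoderm-like cells and primed cluster 1, which had the lowest NODAL and LEFTY1 of the primed clusters. NODAL was still at 6.51 CPM there against 3.03 CPM in LN, and LEFTY1 at 5.33 against 1.28 CPM. LEFTY2 was at 17.5 against 0.384 CPM and CER1 at 1.11 against 0.224 CPM. Feeder RNA accounted for a median of 0.0385% of the primed level of these genes. LEFTY2 was at 190 CPM in primed cluster 4 and 15.6 CPM in primed cluster 0, so levels within the primed library were uneven. A difference in NODAL signalling between the cultures is a hypothesis that was not tested here.

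A further hypothesis was that LN and primed cells vary along a common axis. From LN clusters 1 and 2, 25 genes were taken on each side, among them DUSP6, HMGCS1 and ETV4 on one and ID1, ID2 and OTX2 on the other. In pluripotent-like primed cells, which were not used to pick them, correlation within sides exceeded that between sides by 0.0823, and the largest value in 1000 random gene sets was 0.00599. The result fits a shared axis, but random genes are less coherent than genes that lead clusters, so the comparison is a low bar.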
